A study of Sus scrofa with 8 samples.

How the data were processed

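Total RNA from the liver of lactating and non-lactating sows (Sus scrofa, domestic pig) was measured on Affymetrix Porcine arrays, on which several short oligonucleotide probes together make a probe set for a transcript. Per the series design text, each group had 8 sows, RNA of 2 sows in equal amounts made a pool, and each of the 4 pools per group was hybridised to 1 array, which gives 8 arrays of 16 sows. A pool is therefore the replicate, and the spread between pools is that of averages of 2 animals. All statements below on n refer to pools.

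The authors deposited log2 signals of 24123 probe sets. Per the submitters' processing notes they were made with Affymetrix Expression Console and RMA, a method that corrects background, quantile normalises the arrays and summarises the probes of a set, and the versions are not given in the sources used here. The log2 signals ran from 2.75 to 15.2, and ALB, the brightest of the named genes, sat near the top of that range. The same table carried, per the file headers, the authors' log2 ratio of lactating over control signals, a signed fold change, and a p-value per probe set from a 2-tailed test with equal variances that was not adjusted for the number of probe sets. It also held ratios of lactating over non-lactating pools of equal number, although nothing in the labels says that equal numbers pair the pools. These p-values and ratios were recomputed here from the 8 log2 columns, with a largest difference of 6.11e-09 for the p-values. Another deposited set of log2 values differed from the first by at most 0.005, the rounding of its 2 decimals, and was used as an alternative. No detection calls, scan dates or slide numbers were used here, so batches of that kind were not tested. The number of arrays limits the precision.

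Of the 24123 probe sets, 124 Affymetrix controls were left out, and 23999 were tested. Gene symbols came from the deposited table and were updated through the Sscrofa11.1 gene tables, which matched 9065 probe sets by Entrez identifier, 30 by RefSeq transcript and 4 by accession alone, while 2135 kept their symbol as deposited. A single symbol was assigned to 11234 probe sets, of which 2110 still carry a provisional LOC name, 326 named several genes and 12439 named none, and the last 2 kinds were tested but not named. For each of the 8147 gene symbols, the probe set with the highest mean over all 8 arrays stood for the gene. Positions are those of the deposited table's alignment column, which does not name its assembly in words, and no other coordinates were combined with them.

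The comparison was lactating minus non-lactating pools, fitted with limma 3.58.1 (lmFit and eBayes, without an intensity trend and not robust) in R 4.3.3, with the data.table package (version 1.17.8). Tests were 2-sided, p-values were adjusted over all 23999 probe sets by the method of Benjamini and Hochberg, and an adjusted p below 0.05 counted as changed. Adjusted p-values of single genes are from this limma fit. Lists of genes, 35 in all, and the rule for named genes were fixed before the data were examined. The 32 lists with at least 5 measured members were tested with limma's camera at a preset correlation between genes of 0.01, adjusted over these lists. Beside camera, the correlation was estimated from the data, limma's fry was run, and the mean log2 signal of each list per pool was compared by an exact permutation test. Gene ontology biological process terms with 10 to 300 measured genes came from the deposited table's annotation and were tested in the same way, 126 terms in all.

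The rule for named genes took the 12 genes with the largest fold in each direction among those with an adjusted p below 0.05 and no overlap between the groups, up to 4 members with the smallest p from each list past the threshold and from each other list described, and 11 genes whatever their values: ALB, PRLR, GHR, IGF1, PPARA, CPT1A, FASN, SREBF1, PCK1, FGF21 and 1 that is not reported here. No probe set carried the symbol FGF21. The lists described although they did not pass the test (acute phase proteins, urea cycle and amino acid catabolism, lipoprotein assembly and uptake, the growth hormone, prolactin and insulin axis, NRF2 targets, the circadian clock, amino acid transport and serine synthesis, complement and coagulation) were chosen after their values were seen. These rules gave 121 genes. Of the 60 other probe sets of 37 of these genes, 24 gave the same sign and the same side of the threshold, 24 gave the same sign with only 1 of the pair past the threshold, and 12 gave the opposite sign, for APOB, CDH5, LPL, ORM1, PDK3, PPARA, SLA-DRB1, SLC1A1, SPARC and TXNRD1. SLA genes, FCGR3A, haemoglobin and other multigene family members are uncertain because probes can hybridise to several members.

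The scripts were tested on simulated data with the real means and variances of the 23999 probe sets. For lactating against non-lactating pools, with 200 probe sets changed, limma recovered 52% of those changed by 0.5 on the log2 scale, 78% of those changed by 1, 98% of those changed by 1.5 and 100% of those changed by 2. There were 7 false calls among 171, and 0 calls when nothing was changed. The simulated values were independent between probe sets, while probe sets on real arrays vary together, so these rates need not hold for the data.

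RNA integrity was read from the array's control probe sets, which measure the 3' and the 5' end of the pig GAPDH, actin and EF1a transcripts separately. The 3' minus 5' log2 signal is larger where RNA is more degraded or its reverse transcription is shorter. Its mean over the 3 transcripts was used as a covariate in an alternative chosen after seeing the data, and GAPDH alone, actin alone and a scaled sum of both were tried before it. Other alternatives were variances with an intensity trend, filters on dim probe sets, cyclic loess, median centring, array weights, the replicate number as a block, other thresholds and tests, the mean of all probe sets of a gene, and leaving out each pool in turn. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.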

Results

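Liver RNA of lactating and non-lactating sows was compared to find which transcripts differ in abundance between the states. Each group had 4 pools, each made of RNA from 2 sows. The mean log2 signal of the 8 arrays lay between 6.78 and 6.79. Correlations between arrays, taken across probe sets, which are not independent replicates, were 0.992 to 0.994 within the non-lactating group, 0.991 to 0.994 within the lactating group and 0.984 to 0.991 between the groups. The first principal component held 35.8% of the variance and separated the groups, with scores of -31.4 to -10.9 in non-lactating pools and 11.6 to 24.0 in lactating pools. Non-lactating pool 1 lay farthest from the centre on this component.

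Lactating livers differed from non-lactating livers in 1643 of 23999 probe sets, of which 897 were higher and 746 lower in lactating pools (limma, adjusted p below 0.05). At the level of genes, 704 of 8147 differed, 499 higher and 205 lower. Most differences were small, with a median absolute log2 difference of 0.51 among the changed probe sets, 537 changed by 1.5-fold or more and 70 by 2-fold or more. In 15.3% of all probe sets the 4 values of one group did not overlap the 4 of the other, against 2.86% by chance. The count depended on single pools. The number of probe sets changed in lactation was 406 without non-lactating pool 1, 646 without non-lactating pool 4, 872, 775 and 598 without lactating pools 2, 3 and 4, with 483 lower probe sets in place of 746 without non-lactating pool 2. The number of genes changed in lactation was 159, 255, 355, 315 and 247 in the same order and 468 without non-lactating pool 3, with 123 lower genes in place of 205 without non-lactating pool 2. In the authors' deposited table, 4982 probe sets had an unadjusted p below 0.05, and 2074 of these also had a fold change of 1.3 or more, 1081 higher and 993 lower.

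The 3' minus 5' signals, a reading of RNA integrity, were lower on average in lactating pools for all 3 control transcripts, although none passed after adjustment. The 3' minus 5' log2 signal of GAPDH was 3.71 ± 0.53 (SD, n = 4) in non-lactating pools and 2.63 ± 0.27 (SD, n = 4) in lactating pools, without overlap (exact permutation test, 2-sided p = 0.0286, the smallest that 4 against 4 allow, adjusted over 3 transcripts 0.0857). Actin gave 6.50 ± 0.37 against 5.88 ± 0.38 (SD, n = 4 each, exact permutation p = 0.0571), and EF1a gave 3.19 ± 0.30 against 2.72 ± 0.26 (SD, n = 4 each, exact permutation p = 0.0857), both with an adjusted p of 0.0857. The GAPDH gene was itself higher in lactating pools, by 0.39 (limma adjusted p = 0.0354). Its 3' control signal was bright and also higher, at 13.9 to 14.2 in lactating against 13.5 to 13.8 in non-lactating pools. Whether the change of this transcript affects its 3' minus 5' signal was not tested. The mean of the 3 transcripts was 4.47 ± 0.40 in non-lactating and 3.75 ± 0.29 in lactating pools (SD, n = 4 each), without overlap (exact permutation p = 0.0286, not adjusted). It was highest in non-lactating pool 1, at 5.02, and lowest in lactating pool 4, at 3.34. This measure is therefore confounded with lactation in these pools. With this mean as a covariate, chosen after seeing the data, 0 probe sets passed limma's threshold, while 2474 had an unadjusted p below 0.05. All 1643 changed probe sets, selected on these same arrays, kept their sign, with a median ratio of 0.80 between their differences with and without the covariate and a median ratio of 1.56 between the standard errors of all probe sets.

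**Figure D1:**
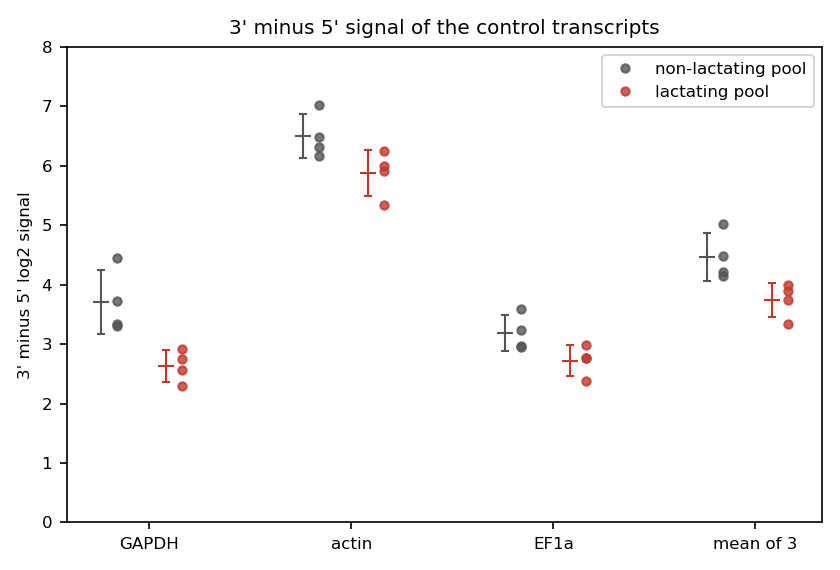
The 3' minus 5' log2 signal (vertical axis) of the GAPDH, actin and EF1a control probe sets and their mean in each pool (points), with the mean and SD of 4 pools per group beside the points. GAPDH separates the groups, with means of 3.71 in non-lactating and 2.63 in lactating pools.

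Among single genes, MYCN, a transcription factor of the MYC family, showed the largest difference. Its log2 signal was 8.88 ± 0.72 (SD, n = 4) in non-lactating pools and 5.59 ± 0.87 (SD, n = 4) in lactating pools, so that it fell by 3.28 ± 0.44 (SE), or 9.73-fold (limma adjusted p = 0.0102). The lactating mean lay close to 5.47, the cut of a filter on the dimmest probe sets, and no background level was used here, so this is a fold of signals that can understate the fold of transcript. The probe set aligned to chromosome 3, positions 112791375 to 112792207, on the minus strand. SLC1A1, a glutamate transporter of epithelia, fell by 1.44 ± 0.19 (SE), and 1 of its 3 other probe sets fell as well. NOV, a secreted matricellular protein, fell by 1.39 ± 0.14 (SE), and ITGB3, the integrin beta 3 subunit, fell by 1.23 ± 0.19 (SE). Further genes lower in lactating pools were PLAC8, FABP3, a fatty acid binding protein, CA3, the cytosolic carbonic anhydrase III, TRPC1, SERPINA6, the corticosteroid-binding globulin of plasma, a sodium-coupled neutral amino acid transporter 1-like gene (LOC100525464), a haemoglobin alpha-like gene (LOC100522428) and ARNTL, with log2 differences of -1.36 to -1.02.

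Of the genes higher in lactating pools, MFSD2A, a transporter of lysophosphatidylcholine, rose by 1.98 ± 0.37 (SE) on the log2 scale, or 3.95-fold (adjusted p = 0.0185), from 6.90 ± 0.38 to 8.88 ± 0.85 (SD, n = 4 each). PMM1, a phosphomannomutase, rose by 1.89 ± 0.41 (SE). CITED1, a transcriptional coregulator on chromosome X (positions 57492678 to 57498057), rose by 1.69 ± 0.19 (SE), with an adjusted p of 0.00863. A gene like VPS13D (LOC100514774) rose by 1.66 ± 0.26 (SE). ABHD5, an activator of triglyceride lipase, rose by 1.35 ± 0.26 (SE), and EGFLAM, an extracellular matrix protein, by 1.22 ± 0.14 (SE), while its other probe set gave 0.26 (adjusted p = 0.201). SLC5A6, the sodium-dependent multivitamin transporter, rose by 1.04 ± 0.13 (SE) and on its other probe set by 1.32. LBP, CRP, ANK3, KDELR3 and a gene like NUDT7 (LOC100519193) completed the 12, with log2 differences of 1.05 to 1.48. Of the 84 named genes past the threshold, 24 passed it with any single pool left out, among them MYCN, SLC1A1, NOV, ITGB3, TRPC1, SERPINA6, ARNTL, CITED1, EGFLAM, ANK3, SLC5A6 and LOC100514774. The other 60 did not pass without at least 1 pool, 55 of them without non-lactating pool 1, 45 without non-lactating pool 4 and 42 without lactating pool 4. None changed sign, which is weak evidence for genes selected on these same arrays.

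**Figure D2:**
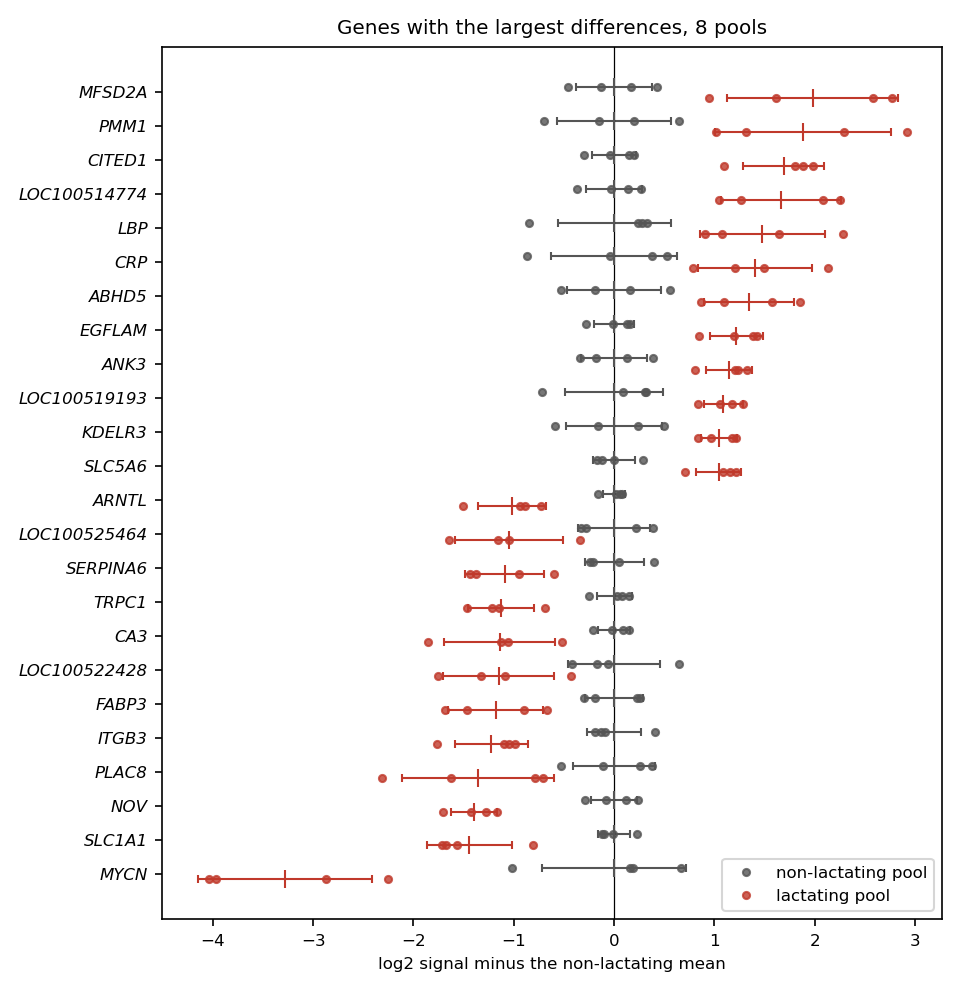
The log2 signal of each pool minus the non-lactating mean (horizontal axis) for the 12 genes with the largest fold in each direction, with the group mean and SD of 4 pools as bars. The groups do not overlap for any of these genes, and MYCN stands lowest, with a difference of -3.28.

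Gene lists fixed before the data were examined were shifted against the other genes in 15 of 32 cases, 9 upward and 6 downward (limma camera, adjusted p below 0.05 at the preset correlation). With a correlation estimated from the data 0 of the 32 passed, with adjusted p-values of 0.320 to 0.494 for the 15, and fry, which asks whether a list moves on balance one way, called 7, of which endothelial markers were the only lower one. In an exact permutation test of the list scores per pool, 7 of the 15 reached the smallest p of 0.0286, and 0 of the 32 passed the adjustment, for which 19 lists at that p would have been needed. One other split of the 8 pools also gave 15 lists, with a median of 8 over the 34 other splits. With the 3' minus 5' covariate 10 lists passed, 7 of the 15 and 3 that had not passed before (neutrophil and cytochrome P450 lists, lower, and cholangiocyte markers, higher). The 8 lists that no longer passed were beta-oxidation (median 0.22 from 0.28, adjusted p = 0.0506), gluconeogenesis and glycogen (0.24 from 0.15, 0.0506), glycolysis (0.25 from 0.30, 0.101), PPAR alpha targets (0.27 from 0.28, 0.285), fatty acid synthesis (0.16 from 0.30, 0.285), interferon-stimulated genes (-0.05 from -0.25, 0.342), antigen presentation (-0.03 from -0.07, 0.458) and the proteasome (-0.0004 from 0.25, 0.862). The score difference went from 0.23 ± 0.10 to 0.31 ± 0.16 (SE) for gluconeogenesis and glycogen, from 0.23 ± 0.04 to 0.16 ± 0.05 (SE) for glycolysis, from 0.43 ± 0.12 to 0.33 ± 0.20 (SE) for PPAR alpha targets, from 0.29 ± 0.19 to 0.12 ± 0.30 (SE) for fatty acid synthesis and from -0.22 ± 0.12 to -0.10 ± 0.20 (SE) for interferon-stimulated genes. The statements on lists that follow hold within these limits.

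**Figure D3:**
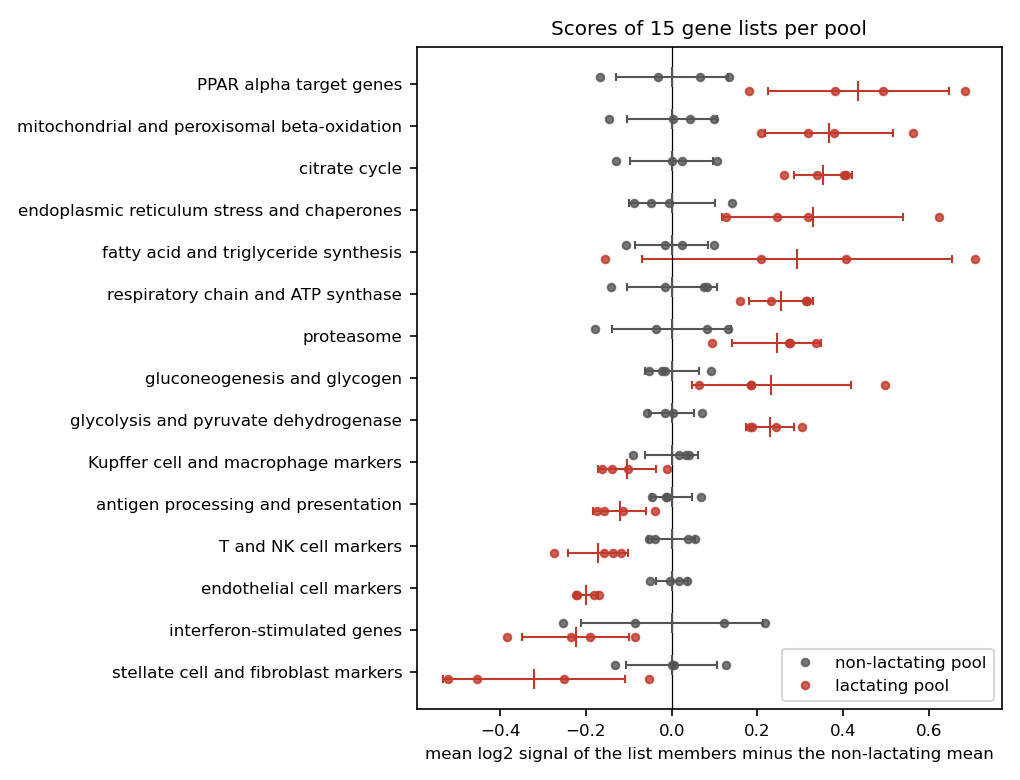
The mean log2 signal of the members of each of the 15 lists past the camera threshold, per pool, minus the non-lactating mean (horizontal axis), with the group mean and SD of 4 pools as bars. The citrate cycle list separates the groups, with a difference of 0.35, while the fatty acid and triglyceride synthesis list overlaps.

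Genes of the citrate cycle, which oxidises acetyl groups in mitochondria, were higher together in lactating pools. All 16 measured members had positive differences, 8 passed the threshold over all probe sets and 13 when adjusted over the list alone, and the median difference was 0.38 (limma camera adjusted p = 3.90e-07, adjusted p = 0.365 with an estimated correlation). IDH2, the mitochondrial NADP-dependent isocitrate dehydrogenase, rose by 0.49 ± 0.08 (SE), and the malate dehydrogenases MDH1 and MDH2 rose by 0.54 ± 0.10 (SE) and 0.52 ± 0.11 (SE). SDHD, a succinate dehydrogenase subunit, rose by 0.41 ± 0.09 (SE). With the 3' minus 5' covariate the score difference of the list went from 0.35 to 0.22 ± 0.06 (SE).

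In the respiratory chain and ATP synthase list, 46 of 48 members had positive differences and the median was 0.24 (camera adjusted p = 2.88e-08, adjusted p = 0.365 with an estimated correlation). Over all probe sets 9 members rose and none fell, and adjusted over the list alone 29 rose and 2 fell. NDUFS1, NDUFA7 and NDUFS6, subunits of complex I, rose by 0.54 ± 0.09, 0.55 ± 0.11 and 0.54 ± 0.11 (SE), and UQCRB of complex III rose by 0.45 ± 0.09 (SE). The second probe set of NDUFS6, a dim one, gave 0.0025. With the covariate the score difference went from 0.26 to 0.14 ± 0.09 (SE).

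Beta-oxidation of fatty acids was represented by 19 genes, of which 18 had positive differences with a median of 0.28 (camera adjusted p = 1.62e-04, adjusted p = 0.365 with an estimated correlation). Over all probe sets 5 rose, and 10 when adjusted over the list alone. SLC25A20, the mitochondrial carnitine and acylcarnitine carrier, rose by 0.91 ± 0.14 (SE), ETFDH by 0.68 ± 0.14 (SE), HADHB by 0.57 ± 0.11 (SE) and ACADL by 0.49 ± 0.12 (SE). With the covariate the score difference went from 0.37 to 0.21 ± 0.12 (SE). The list of PPAR alpha targets, which shares members with beta-oxidation, had 13 of 15 positive differences and a median of 0.28 (camera adjusted p = 0.0219, adjusted p = 0.365 with an estimated correlation). Its only member past the threshold, over all probe sets and when adjusted over the list alone, was SLC25A20. CPT1A, which makes acylcarnitines at the outer mitochondrial membrane, was 2.46-fold of the non-lactating level (SE of the log2 difference 0.42) and did not pass (adjusted p = 0.0961), with an SD of 1.04 among lactating and 0.27 among non-lactating pools. ACSL1 (0.28 ± 0.09 SE) and CREB3L3 (0.47 ± 0.18 SE) did not pass either, although another probe set of CREB3L3 did. The receptor gene PPARA had -0.07 ± 0.10 (SE) at a low signal.

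Genes of fatty acid and triglyceride synthesis had positive differences in 15 of 16 cases with a median of 0.30 (camera adjusted p = 0.0177, adjusted p = 0.365 with an estimated correlation). AGPAT2 and LPIN2, enzymes of glycerolipid synthesis, rose by 0.50 ± 0.10 (SE) and 0.48 ± 0.11 (SE) and were the only members past the threshold, also when adjusted over the list alone. FADS1 (0.68 ± 0.24 SE), DGAT2 (0.35 ± 0.13 SE), FASN, fatty acid synthase (0.32 ± 0.34 SE) and SREBF1 (0.18 ± 0.09 SE) did not pass. The difference of FASN ran from 0.0034 without lactating pool 4 to 0.58 without lactating pool 3. The median of the list ran from 0.16 without lactating pool 4, where the list did not pass (camera adjusted p = 0.111), to 0.47 without lactating pool 3, whose score lay 0.15 below the non-lactating mean.

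Glycolysis and pyruvate dehydrogenase genes were split, with 8 of 12 positive differences, 5 members that rose over all probe sets, 7 adjusted over the list alone, none that fell and a median of 0.30 (camera adjusted p = 0.0219, adjusted p = 0.365 with an estimated correlation). PDK3, a kinase that inhibits pyruvate dehydrogenase, rose by 0.53 ± 0.09 (SE), TPI1 by 0.53 ± 0.10 (SE), PGAM1 by 0.38 ± 0.08 (SE) and GAPDH by 0.39 ± 0.09 (SE). A second, dim probe set of PDK3 gave -0.10. Among 13 gluconeogenesis and glycogen genes the median was 0.15 (camera adjusted p = 0.0281, adjusted p = 0.365 with an estimated correlation). SLC2A2, the liver glucose transporter, rose by 0.56 ± 0.09 (SE) as the only member past the threshold, with 4 when adjusted over the list alone. PC, pyruvate carboxylase, had 0.71 ± 0.20 (SE, adjusted p = 0.0632), UGP2 0.48 ± 0.16 (SE), LDHA 0.31 ± 0.10 (SE) and PCK1, phosphoenolpyruvate carboxykinase, 0.06 ± 0.59 (SE). The camera call of this list was lost without non-lactating pool 2 (median 0.17, adjusted p = 0.0510) and without lactating pool 2 (median 0.10, adjusted p = 0.102), with cyclic loess (median 0.09, adjusted p = 0.110) and without the dimmest probe sets (median 0.15, adjusted p = 0.0571), and the median was highest, at 0.32, without lactating pool 4.

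Chaperones and other genes of the endoplasmic reticulum stress response had 16 of 17 positive differences with a median of 0.25 (camera adjusted p = 9.03e-04, adjusted p = 0.490 with an estimated correlation). Over all probe sets 4 rose, and 5 when adjusted over the list alone: CRELD2 rose by 0.89 ± 0.19 (SE), DNAJB11 by 0.70 ± 0.14 (SE), MANF by 0.65 ± 0.14 (SE) and HSP90B1, the chaperone GRP94, by 0.50 ± 0.10 (SE). Proteasome subunits had 24 of 26 positive differences with a median of 0.25 (camera adjusted p = 1.62e-04, adjusted p = 0.494 with an estimated correlation). Over all probe sets 5 rose, and 10 when adjusted over the list alone, with PSMA5 at 0.58 ± 0.14 (SE), PSMD14 at 0.51 ± 0.11 (SE), PSMA6 at 0.46 ± 0.09 (SE) and PSMD12 at 0.36 ± 0.08 (SE). The proteasome score difference went from 0.24 to 0.03 ± 0.08 (SE) with the 3' minus 5' covariate. The 95% interval over pools, -0.18 to 0.25, covers both no difference and the difference without the covariate. This fit therefore cannot tell whether RNA integrity accounts for the proteasome difference. The median of the proteasome list was 0.16 without non-lactating pool 1.

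Markers of cells other than hepatocytes were lower in lactating pools for 4 of the lists. Stellate cell and fibroblast markers had 12 of 16 negative differences and a median of -0.42 (camera adjusted p = 8.04e-04, adjusted p = 0.365 with an estimated correlation). The small proteoglycans DCN and BGN fell by 0.88 ± 0.15 (SE) and 0.45 ± 0.08 (SE) over all probe sets, 5 members fell when adjusted over the list alone, and SPARC (-0.42 ± 0.12 SE) and POSTN (-0.57 ± 0.17 SE) did not pass over all probe sets. Endothelial markers had 11 of 12 negative differences with a median of -0.13 (camera adjusted p = 0.00199, adjusted p = 0.320 with an estimated correlation). Here 4 fell over all probe sets and the same number adjusted over the list alone: TEK, the angiopoietin receptor, fell by 0.61 ± 0.13 (SE), PECAM1 by 0.43 ± 0.07 (SE, another probe set -0.11), CLDN5 by 0.40 ± 0.09 (SE) and CDH5 by 0.33 ± 0.08 (SE). The other TEK probe sets, which were dim, gave -0.05 and -0.08, and a dim one of CDH5 gave 0.0016. With each pool left out in turn, PECAM1 passed in 8 of 8 fits, TEK in 5, CDH5 in 2 and CLDN5 in 1. Kupffer cell and macrophage markers had 14 of 20 negative differences with a median of -0.13 (camera adjusted p = 0.0160, adjusted p = 0.365 with an estimated correlation), 3 that fell over all probe sets and, adjusted over the list alone, 4 that fell and 1 that rose. FCER1G fell by 0.41 ± 0.08 (SE), MRC1 by 0.39 ± 0.08 (SE) and FCGR3A by 0.29 ± 0.07 (SE), and CTSS had -0.27 ± 0.08 (SE, adjusted p = 0.0802). The call of FCGR3A was lost whichever pool was left out, and with the replicate number as a block (limma adjusted p = 0.0596). T and NK cell markers had 16 of 18 negative differences with a median of -0.10 (camera adjusted p = 0.00440, adjusted p = 0.365 with an estimated correlation). KLRK1, a receptor of NK cells, fell by 0.77 ± 0.17 (SE) and CD8A by 0.60 ± 0.13 (SE), 3 members fell when adjusted over the list alone, and LCK (-0.47 ± 0.13 SE) and CD3G (-0.27 ± 0.09 SE) did not pass. With fry the endothelial list passed (adjusted p = 6.73e-04), and the stellate (0.0668), Kupffer (0.0690) and T and NK cell lists (0.0526) did not. With the 3' minus 5' covariate the joint score of these 4 lists went from -0.19 to -0.15 ± 0.05 (SE), endothelial markers from -0.20 to -0.18 ± 0.04, stellate markers from -0.32 to -0.23 ± 0.19, Kupffer markers from -0.10 to -0.04 ± 0.07 and T and NK cell markers from -0.17 to -0.19 ± 0.08 (SE).

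Antigen processing and presentation genes had 15 of 24 negative differences with a median of -0.07 (camera adjusted p = 0.0177, adjusted p = 0.365 with an estimated correlation), and the 4 that fell over all probe sets, of 6 adjusted over the list alone, belong to class II. SLA-DRB1 fell by 0.70 ± 0.10 (SE), SLA-DQB1 by 0.67 ± 0.10 (SE), SLA-DRA by 0.62 ± 0.10 (SE) and SLA-DMA by 0.43 ± 0.11 (SE). These are uncertain as members of a polymorphic family, the 7 other SLA-DRB1 probe sets ranged from -1.97 to 0.07, and the table titles the SLA-DMA probe set as DO alpha. With the covariate the score difference of the list went from -0.12 to -0.02 ± 0.03 (SE). Interferon-stimulated genes had 17 of 19 negative differences with a median of -0.25 (camera adjusted p = 0.0160, adjusted p = 0.490 with an estimated correlation) but none passed the threshold, over all probe sets or adjusted over the list alone. RSAD2 had -0.91 ± 0.26 (SE, adjusted p = 0.0657), MX2 -0.20 ± 0.07 (SE), IFI44L -0.38 ± 0.18 (SE) and STAT2 0.21 ± 0.10 (SE). Without non-lactating pool 2 the camera adjusted p of this list was 0.0692, and without non-lactating pool 1 its median was -0.15.

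Several lists without a shift as a whole held single genes that changed. Of 18 acute phase proteins, which the liver secretes in inflammation, 4 rose and 1 fell, over all probe sets and adjusted over the list alone, with a median of 0.14 (camera adjusted p = 0.102, and 0.0332 and 0.0460 without lactating pool 3 or 4). The median ran from 0.07 without lactating pool 1 to 0.25 without lactating pool 3. LBP, the lipopolysaccharide binding protein, rose by 1.48 ± 0.33 (SE), CRP by 1.41 ± 0.33 (SE), APCS by 0.97 ± 0.19 (SE) and ORM1 by 0.57 ± 0.10 (SE), while SERPINA1, alpha-1-antitrypsin, fell by 0.32 ± 0.06 (SE). A dimmer ORM1 probe set gave -0.45. Among 31 complement and coagulation genes (median -0.01, camera adjusted p = 0.272, and lower at 0.0113 with cyclic loess), CFD fell by 0.58 ± 0.09 (SE) and C2 rose by 0.61 ± 0.14 (SE), with 1 higher and 2 lower adjusted over the list alone. PROC (-0.24 ± 0.07 SE) and F12 (-0.34 ± 0.11 SE) did not pass over all probe sets.

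In the growth hormone, prolactin and insulin axis (20 genes, median 0.0009 and mean 0.08, while camera put the list lower, adjusted p = 0.942), IGF1, the insulin-like growth factor that the liver secretes, rose by 0.84 ± 0.16 (SE, adjusted p = 0.0195), or 1.80-fold. A second IGF1 probe set rose by 0.89 and another gave 0.0078, and without non-lactating pool 1 the adjusted p of IGF1 was 0.0597. DIO1, the type I iodothyronine deiodinase, rose by 0.76 ± 0.18 (SE). IGFBP3 (-0.45 ± 0.12 SE, adjusted p = 0.0527), SOCS1 (0.93 ± 0.29 SE), GHR (-0.10 ± 0.18 SE) and PRLR, the prolactin receptor (-0.09 ± 0.14 SE), did not pass, and adjusted over the list alone 3 were higher and 1 lower. Of 14 genes of lipoprotein assembly and uptake (median 0.19, camera adjusted p = 0.129, and 0.0498 without lactating pool 4), APOC2 rose by 0.39 ± 0.10 (SE), a call that was lost whichever pool was left out. Adjusted over the list alone, 3 higher and 1 lower passed. APOA4 had the widest spread, with 2.34 ± 0.70 (SE) that did not pass (adjusted p = 0.0767) and lactating pools from 7.38 to 11.4. APOB (0.29 ± 0.08 SE) and LPL (-0.26 ± 0.08 SE) did not pass. ALB, albumin, was near the highest signal on the array in both groups, with a difference of -0.0077 ± 0.062 (SE).

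Amino acid genes changed in both directions. Of 22 urea cycle and amino acid catabolism genes 4 rose and 1 fell, with 5 and 2 adjusted over the list alone and a median of 0.17 (camera adjusted p = 0.127, and 0.0460 without lactating pool 4). GOT2, mitochondrial aspartate aminotransferase, rose by 0.50 ± 0.08 (SE), BCKDK, the kinase that inhibits branched-chain ketoacid oxidation, by 0.43 ± 0.09 (SE) and GLUD1 by 0.38 ± 0.09 (SE), while IVD, isovaleryl-CoA dehydrogenase, fell by 0.98 ± 0.25 (SE). The 2 other IVD probe sets did not pass. The list of amino acid transport and serine synthesis (8 genes, median 0.05, camera adjusted p = 0.364) had a score difference of 0.34 ± 0.07 (SE). Its exact permutation p was 0.0286, the smallest possible, and 0.102 adjusted over the lists. In it PHGDH, the first enzyme of serine synthesis, rose by 0.59 ± 0.14 (SE), and 2 higher and 1 lower passed adjusted over the list alone. PSPH, the last enzyme of that pathway, had 1.59 ± 0.43 (SE, adjusted p = 0.0553), ASNS 0.76 ± 0.30 (SE) and SLC1A5 -0.29 ± 0.10 (SE).

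Of 27 NRF2 target and antioxidant genes (median 0.11, camera adjusted p = 0.161) 3 rose and 2 fell, with 7 and 2 adjusted over the list alone. PRDX1 rose by 0.62 ± 0.12 (SE) and TXNRD1 by 0.43 ± 0.10 (SE), while GCLC, the catalytic subunit of the enzyme that limits glutathione synthesis, fell by 0.72 ± 0.16 (SE) and PRDX6 by 0.40 ± 0.08 (SE). One of the other TXNRD1 probe sets gave -0.11. Only 5 circadian clock genes were measured (median -0.0037, camera adjusted p = 0.333). ARNTL, the clock's activating transcription factor, fell by 1.02 ± 0.15 (SE, adjusted p = 0.0120) and CRY1, a repressor in the clock, by 0.72 ± 0.15 (SE), while RORA (0.25 ± 0.09 SE) and BHLHE40 (0.47 ± 0.25 SE) did not pass over all probe sets, and 1 higher and 2 lower passed adjusted over the list alone. The labels give no time of day of sampling.

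In the open search over 126 gene ontology terms, 9 passed at the preset correlation, 4 higher and 5 lower, and 0 with an estimated correlation (adjusted p of 0.615 to 0.658 for the 9). The tricarboxylic acid cycle (13 genes, median 0.40, camera adjusted p = 7.11e-06), protein folding (14 genes, median 0.30, adjusted p = 0.00334), glycolysis (12 genes, median 0.38) and cell redox homeostasis (11 genes, median 0.20) were higher. Immune response (72 genes, median -0.10, adjusted p = 0.00235), antigen processing and presentation (20 genes, median -0.19), protein autophosphorylation (13 genes, median -0.20), calcium ion transport (18 genes, median -0.13) and signal transduction (154 genes, median -0.06) were lower. The count ranged from 5 without lactating pool 2 to 15 without non-lactating pool 2, and it was 3 with the 3' minus 5' covariate.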

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

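The tests of list scores, of predicted differences and of probe set position per pool were chosen after the results were seen, while the counts over splits and the other tests by probe set position were planned before their results. Chance is unlikely to explain the number of probe sets changed in lactation. Only 1 of the 35 splits of the 8 pools gave as many, the real one with 1643, and the highest other split gave 3. A share of 1 in 35 is the smallest these splits allow, and the shares were not adjusted for the several counts tested. Genes, counted from the same probe sets, gave 1 of 35 splits as well, with 704 in the real one and 1 in the highest other. Chance cannot be excluded for the number of lists, since 2 of 35 splits gave as many. These were the real one with 15 and a split with 15 that exchanges non-lactating pool 3 with lactating pool 4. Nor can it be for gene ontology terms, since 2 of 35 splits gave 9, the other one exchanging non-lactating pool 2 with lactating pool 2.

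The control probe sets gave a signal outside the main measurement, a mean 3' minus 5' log2 signal of 3.75 in lactating and 4.47 in non-lactating pools, a difference of -0.72. This measure includes GAPDH, whose own transcript was higher in lactating pools. Differences predicted from each probe set's slope on this measure within the groups correlated across probe sets with the observed ones at 0.275, with 5 of 100 permutations as high or higher and a 95th percentile of 0.266, so RNA integrity may contribute to the differences. By probe set position, 54.1% of 314 genes had their 5' probe set higher against their 3' one in lactating pools, with a mean of 0.0364 (planned permutation of signs over genes, p = 0.0258), and non-lactating pool 1 showed the shape of lower integrity (61.5%, mean -0.0618, p = 1e-04), but genes share the arrays, and with pools as replicates the 95% interval was -0.06 to 0.13 (exact permutation p = 0.343), which leaves this open. For the citrate cycle the score difference with the covariate was 0.217 (95% interval 0.06 to 0.38), from 0.353 without it. The covariate thus did not account for all of the difference in this fit, but it may correct for integrity only in part. Its values did not overlap between the groups, at 4.14 or more in non-lactating pools and 4.00 or less in lactating pools. A larger share of hepatocytes stays open too. The energy score rose more than that of hepatocyte secretory markers by 0.221 (95% interval 0.10 to 0.34) without and 0.177 (95% interval -0.02 to 0.38) with the covariate. Markers near the top of the signal range, such as ALB, show a change of share poorly. For the respiratory chain (0.143, 95% interval -0.08 to 0.37, from 0.255) and beta-oxidation (0.207, 95% interval -0.11 to 0.53, from 0.367) the intervals over pools include 0 (camera adjusted p = 0.00256 and 0.0506 with the covariate). Integrity and lactation cannot be told apart for any of the 3 lists, and lactation stays among the open explanations.

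Markers of stellate, endothelial, Kupffer and T and NK cells were lower in lactating pools by a joint score of -0.192, and of -0.152 (95% interval -0.27 to -0.04) with the covariate. The covariate thus did not account for all of the joint difference in this fit, but it may correct for integrity only in part. These lists were joined because they had passed. List by list the interval lay below 0 for endothelial markers (-0.181, 95% interval -0.28 to -0.08). The intervals over pools included 0 for stellate (-0.230, 95% interval -0.73 to 0.27), Kupffer (-0.0386, 95% interval -0.21 to 0.13) and T and NK cell markers (-0.188, from -0.172, 95% interval -0.38 to 0.005). Camera at the preset correlation passed these 3 with the covariate (adjusted p = 0.0283, 0.0445 and 0.00256). Integrity and lactation cannot be told apart for any of the 4 lists, because the covariate does not overlap between the groups. B and plasma cell markers, outside these lists, went from -0.164 to 0.00239 (95% interval -0.23 to 0.24). The stellate minus cholangiocyte score differed by -0.390 (95% interval -0.71 to -0.07), and by -0.654 (95% interval -1.07 to -0.24) with the covariate, which argues against an equal loss of all cells other than hepatocytes. A smaller share of these 4 kinds of cell, or less of these transcripts per cell, in lactation may account for it, and neither was tested.

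In both groups pools 1 and 2 stood apart from pools 3 and 4 on the second principal component, which held 19.7% of the variance. The differences between these pools correlated between the groups at 0.305 across probe sets, the highest of 18 pairings (1 of 18 as high, highest other 0.127), and 18 pairings are too few for a share under 0.05. This grouping was chosen after the same arrays were seen, so its high rank is no separate support for it. The values by probe set position that follow share this limit. In pools 1 and 2 the 5' probe set was lower against the 3' one in 67.2% of 314 genes, with a mean of -0.0780 and, with pools as replicates, a 95% interval of -0.14 to -0.02 (-0.16 to 0.01 without non-lactating pool 1), so RNA integrity may contribute here too. Removing the 3' minus 5' slope left a correlation of 0.0258, which decides nothing, because that measure itself runs with these pools (alignment 0.581). No biological explanation was tested, since the labels name no difference between these pools.

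In 11 of 324 groups of 4 pools tested 1 pool stood far from the other 3, with a gap over a range beyond Dixon's 95% value, and about 16.2 were to be found by chance. Lactating pool 1 was that pool for CRELD2 (10.3, ratio 0.925), APCS (13.8, ratio 0.835), GLUD1 (14.0, ratio 0.851) and PRLR (4.79, ratio 0.872). Lactating pool 3 was the highest for SLC1A1 (8.88, ratio 0.832) and UQCRB (11.3, ratio 0.890), and lactating pool 2 the lowest for ITGB3 (7.12, ratio 0.862). Non-lactating pool 1 was the lowest for LBP (6.74, ratio 0.925), non-lactating pool 3 the highest for CD3G (5.43, ratio 0.874) and CLDN5 (7.45, ratio 0.861), and non-lactating pool 4 the highest for ITGB3 (9.30, ratio 0.8291).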

How the results depend on the processing

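The 3' minus 5' covariates, pools 1 and 2 against pools 3 and 4 as a block, the equal-variance test, the permutation of list scores and the matchings of pools were chosen after the data were seen, and the other alternatives before. All 1643 probe sets changed in lactation kept their sign wherever they were tested. This is weak evidence, because they were selected on these same arrays. With other variances, filters, scalings, the other deposited table or array weights, 1377 to 1633 of the 1643 passed, where 1576 to 1869 probe sets passed. The share higher was 54.6%, 49.2% with cyclic loess and 64.4% with median centring.

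With the replicate number as a block 1790 probe sets, 742 genes, 16 lists and 12 gene ontology terms passed. Of the 1643 probe sets 1322 passed, and of the named genes 15 lost their call, with adjusted p-values of 0.0509 (PGAM1) to 0.0749 (LOC100522428), among them LBP, CRP, PLAC8, TEK, CDH5 and HSP90B1, while PC, UGP2, APOA4 and IGFBP3 gained one. Whether equal numbers pair the pools was left open. Deviations from the group means correlated at 0.243, 0.0896, 0.0724 and 0.221 for numbers 1 to 4, 5 of 8 pools correlated best with their own number where 2 are expected by chance, and the mean of 0.156 was reached by 2 of 24 matchings of the pools, the other with 0.159.

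With the mean 3' minus 5' covariate limma called 0 probe sets (0 higher, 0 lower; 2474 at an unadjusted p under 0.05) and 0 genes (0 higher, 0 lower), 4 lists higher and 3 gene ontology terms. GAPDH alone left 1 probe set, lower (0 higher), which is 1 gene, LOC100519082, with 1923 at an unadjusted p under 0.05. Actin alone (3191 unadjusted) and the scaled sum (2487 unadjusted) left 0 probe sets and 0 genes in either direction. With the mean covariate the standard error grew by a median ratio of 1.56. Of the 84 named genes past the threshold without it, 72 stayed beyond 2 standard errors and 0 passed. The 72 are weak evidence, because these genes were selected on these same arrays. Blocking on pools 1 and 2 against 3 and 4 gave 2405 probe sets (1267 higher, 1138 lower), the 1643 among them, and 1016 genes (679 higher, 337 lower).

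An unadjusted p under 0.05 with a fold of 1.3 gave 2439 probe sets (1231 higher, 1208 lower) and 930 genes (593 higher, 337 lower). An adjusted p with a fold of 1.5 gave 537 probe sets (283 higher, 254 lower) and 198 genes (126 higher, 72 lower). The Welch and the equal-variance test, each adjusted, called 0 probe sets and 0 genes in either direction. Unadjusted, Welch gave 4425 probe sets and 1887 genes, and equal variances gave 4964 (2637 higher, 2327 lower) and 2076 genes (1332 higher, 744 lower). Neither borrows variance across probe sets as limma does. With an estimated correlation camera called 0 lists (0 higher, 0 lower) and 0 gene ontology terms, fry called 7 lists (1 lower), and the exact permutation of list scores called 0.

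Leaving out each pool gave 406 to 1424 probe sets (207 to 746 higher, 199 to 678 lower), lowest without non-lactating pool 1, 159 to 616 genes (103 to 414 higher, 56 to 202 lower), 14 to 18 lists (8 to 11 higher, 6 to 7 lower) and 5 to 15 gene ontology terms.

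Signs changed for genes that did not pass: PCK1 with cyclic loess (-0.00426), array weights (-0.13) and single pools left out (-0.54 to 0.51), ALB with median centring (0.023) and pools left out (-0.013 to 0.00157), PRLR (-0.15 to 0.029) and GHR (-0.27 to 0.019) with pools left out. The ribosomal protein list went lower with cyclic loess (-0.052, adjusted p = 0.0321), and the cause was not tested. Dim probe sets near background limit what can be seen, and no background level per probe set was used here.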

Other observations

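Single genes named here from the lists were chosen after their values were seen, as was the comparison of probe sets with and without a symbol. Some lists had too few measured members for a test. BDH1, the mitochondrial hydroxybutyrate dehydrogenase, rose by 0.63 ± 0.14 (SE, limma adjusted p = 0.0279). Of 3 genes of carnitine synthesis and uptake 1 (SLC25A20) rose over all probe sets and 3 adjusted over the list alone, with a median of 0.27. The 3 erythroid markers had a median of -0.19 and none passed in either way.

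Other lists did not pass the test. Cholesterol synthesis and uptake (15 genes, median 0.07 and mean 0.02, placed lower by camera, adjusted p = 0.942), cytosolic ribosomal proteins (51 genes, median 0.03, adjusted p = 0.662), cholangiocyte markers (12 genes, median 0.02, adjusted p = 0.942), B and plasma cell markers (8 genes, median -0.09, adjusted p = 0.194) and NF-kappa B, cytokines and chemokines (26 genes, median -0.09, adjusted p = 0.0570) had 0 members past the threshold, over all probe sets or adjusted over the list alone. In the cytochrome P450, conjugation and bile acid list (29 genes, median -0.04 and mean 0.0077, placed lower by camera, adjusted p = 0.852) POR, the electron donor of cytochromes P450, rose by 0.50 ± 0.13 (SE), and 0 passed adjusted over the list alone. In the cell cycle list (21 genes, median 0.04, adjusted p = 0.217, and 0.0428 without lactating pool 2) BIRC5 rose by 0.40 ± 0.07 (SE), the 1 member also past the threshold adjusted over the list alone. Neutrophil markers (12 genes, median -0.07, adjusted p = 0.102) held 1 gene that fell, FCGR3A, which macrophages share and whose call was lost whichever pool was left out. Adjusted over the list alone 2 fell. Hepatocyte secretory markers (14 genes, median 0.03, adjusted p = 0.861) held SERPINA1, which fell, and adjusted over the list alone also APOB on the higher side. With the 3' minus 5' covariate the neutrophil (adjusted p = 0.00343) and cytochrome P450 lists (adjusted p = 0.0211) were lower and cholangiocyte markers higher (adjusted p = 0.0384), and neutrophil markers were also lower without non-lactating pool 1 (0.0347) or lactating pool 4 (0.0460). NF-kappa B passed on the lower side in 8 alternatives, with median centring (adjusted p = 0.0452), array weights (0.0382), the replicate block (0.0359), pools 1 and 2 against 3 and 4 as a block (0.0368), and without non-lactating pool 2 (0.0443) or 4 (0.0277) or lactating pool 1 (0.0339) or 2 (0.0239).

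Probe sets with and without a gene symbol went different ways. Of 914 changed probe sets with a symbol 71.9% were higher in lactating pools, and of 729 without one 32.9% were. The median difference predicted from the 3' minus 5' slopes was 0.0620 for changed probe sets with a symbol and -0.0580 for those without. Over all tested probe sets these medians were 0.0176 and -0.0071. Probe sets with a symbol were also brighter, with a median log2 signal of 7.16 against 6.08. The cause of the split was not tested.

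Between pools 3 and 4 and pools 1 and 2, across both groups, 22 probe sets differed, 5 higher and 17 lower in pools 3 and 4, with 3867 at an unadjusted p under 0.05 (limma). They include 4 genes, LUM (-1.02), RHNO1 (1.20), FGF13 (-1.31) and LOC100512504 (-0.55). Interferon-stimulated genes were lower in pools 3 and 4 with a median of -0.28 (camera adjusted p = 3.11e-04, adjusted p = 0.155 with an estimated correlation). The grouping of these pools was chosen after the same arrays were seen, so these counts and p-values describe it and are no separate support for it.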
